A study of Mus musculus with 6 samples.

How the data were processed

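The series holds 6 samples of Mus musculus, 3 necdin-null and 3 wild-type, and each sample's group and replicate number were taken from its title. Per the labels' protocols, total RNA was extracted with TRI Reagent, 1 µg was labelled with a MessageAmp II-Biotin Enhanced kit, and the label is given as Cy5. The array maker, scanner, background correction and normalization are not given in the sources used here. The table the authors deposited holds 1 intensity per feature and array on a linear scale, for 36227 features without missing values. The deposited intensity columns had already been brought to 1 distribution: after sorting, the 6 columns differed by under 1% at 99.7% of ranks, and their medians, quartiles and maxima also differed by under 1%. This is the form that quantile normalization leaves. Such values cannot show a change in the overall amount of RNA or a shift common to most probes. The lowest deposited intensity was 0.001, held by 0.69% to 0.87% of the features of an array.

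Features are numbered from 1 to 36227, with no gene name, sequence or accession. The table of 49997 mouse RefSeq genes that was used for names has no column with these numbers, so 0 features could be named. The numbers were not read as an order of genes. The test was planned for genes and was run on probes instead. The tests of 32 gene lists, of Ndn and of the genes around it on chromosome 7, and the alternatives that belong to them, could not be run. Control features could not be recognised by name and were kept. A total of 638 features (1.76%), in 11 stretches of the feature order, had nearly the same bright level (mean log2 intensity 10.3, SD 0.14) and look like a control lattice. They were recognised after the data were examined, by a mean log2 intensity between 10 and 10.8 with at least 2 others of that kind within 7 places, and leaving them out was tried as an alternative.

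Intensities under the 5th percentile of all positive values (2.73) were set to it and log2 was taken, so fold changes of dim probes are compressed. No further normalization was applied. Each probe was fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), necdin-null minus wild-type, over all 6 arrays with no covariate, and p-values were adjusted by Benjamini-Hochberg over all probes with a threshold of 0.05. All tests were two-sided. The variance prior had 1.61 degrees of freedom beside 4 residual ones, so that the spread of single probes weighs heavily. The brighter probes are the 18113 probes whose mean log2 intensity over all 6 arrays was above the median of 4.26. The estimated share of unchanged probes used limma's convex decreasing density method. Figures were drawn with matplotlib 3.10.9. The small number of arrays, 3 per genotype, limits the precision. The table gives no spot counts or background values, so their part in the error could not be assessed.

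The rule for named probes was fixed before the data were examined. In each direction it takes probes past the threshold by size of change, then probes by unadjusted p, among the brighter probes whose groups do not overlap. Because the probes have no names, only the first 2 in each direction are given. The fitting procedure was tested on simulated data: in each of 10 runs, values for the 36227 probes were drawn from the observed levels and variances, and 200 probes were changed by 0.5, 1, 2 or 4 on the log2 scale. Changes of 0.5 and 1 were all rises, changes of 2 and 4 were all falls, and values under the floor were set to it.

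Same-numbered samples of the 2 genotypes were checked for pairing through the correlation of their deviations from the group means. The labels do not say that a number marks a litter or a day, and the 3 correlations were below the 0.1 set for pairing, so the main fit has no block. The alternatives were quantile normalization again, median centring, leaving out the dimmest 25% or 50% of the probes, a floor at the 20th percentile, log2(value + 16), a level-dependent robust variance prior, array weights, the replicate number as a block, each array left out in turn, a limit of 1 on the log2 difference, and an unmoderated two-sample test with equal variances. Alternatives added after the data were examined were no added floor, leaving out the lattice features, leaving out probes at the deposited floor, and subtracting a trend with level (lowess, span 0.2) or a running median over 101 places of the feature order.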

Results

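Gene expression was profiled in primary cortical neurons from mouse embryos with and without necdin. Necdin is a protein of the MAGE family that is abundant in postmitotic neurons, and its gene, Ndn, is expressed from the paternal chromosome only. Cortical cells of ICR mice were taken at embryonic day 14.5 and kept in culture for 4 days, when nearly all were MAP2-positive neurons. Total RNA of 3 necdin-null and 3 wild-type animals was hybridised to 1-colour microarrays, 1 array per animal. The spread within a group thus holds differences between animals together with those of culture, labelling and hybridisation. Each array gave an intensity for 36227 features, here called probes. The features carry only a number from 1 to 36227, and none of them could be paired with a gene from the tables used here. The level of Ndn itself, which would check the genotype labels, was therefore not analysed here, nor were the 32 lists of mitochondrial, neuronal, glial, imprinted and other genes that had been fixed beforehand. Results are given for probes by number.

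The 6 arrays had the same intensity distribution as deposited. The median intensity was 19.6 on every array, and the upper quartile was 62.4. Between 250 and 315 probes per array lay at the lowest deposited value of 0.001. No 2 of the 6 columns were identical. Across all probes, log2 intensities of 2 arrays correlated at Pearson r between 0.966 and 0.970 within the necdin-null group, between 0.966 and 0.969 within the wild-type group, and between 0.962 and 0.970 between the genotypes. Among the 18113 probes above the median level (the brighter probes), the root mean square difference between 2 arrays averaged 0.25 (log2) over the 3 wild-type pairs, 0.292 over the 3 necdin-null pairs and 0.306 over the 9 pairs of different genotype. The first principal component of the brighter probes held 39.2% of the variance. All 3 necdin-null arrays had negative scores on it, from -29.9 for replicate 1 to -0.84 for replicate 2, and all 3 wild-type arrays positive scores, from 9.26 to 20.3.

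The comparison that the design implies asks which transcripts differ between necdin-null and wild-type neurons. One probe, number 30933, fell far in every necdin-null culture. Its mean intensity was 475 ± 14.7 (SD, n = 3) in wild-type neurons and 27.8 ± 4.00 (SD, n = 3) in necdin-null neurons. On the log2 scale these were 8.89 ± 0.04 and 4.78 ± 0.22, a difference of -4.11 with a standard error of 0.13. The probe was thus 17.2-fold lower without necdin, with a 95% confidence interval of 13.7 to 21.7-fold. The interval covers only the spread between the arrays of a group, and not the choice of scale. With log2(value + 16), which compresses low intensities, the difference was -3.49. The lowest wild-type value exceeded the highest necdin-null value by 3.89 (log2), against an SD within groups of at most 0.22. In wild-type neurons the probe stood at the 95.6th percentile of all intensities, and in necdin-null neurons at the 58.6th. An intensity above the array median thus remained in all 3 necdin-null cultures. Without background values it cannot be told whether this is transcript or background.

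**Figure D1:**
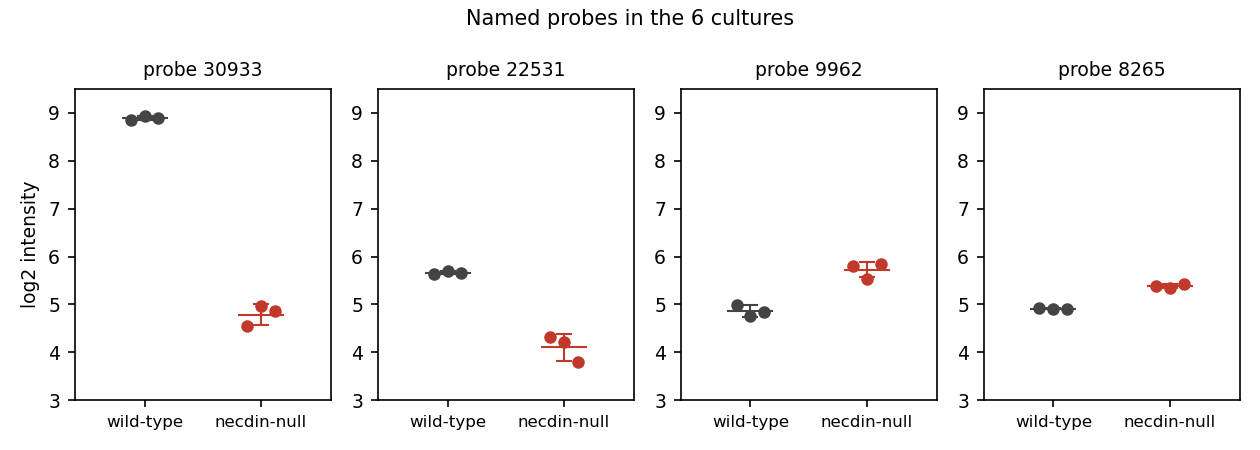
Log2 intensity (vertical axis) of the 4 named probes in the wild-type and necdin-null cultures. Each point is 1 array, the long horizontal line is the group mean and the error bar its SD (n = 3). Probe 30933 lies at 8.89 in wild-type and 4.78 in necdin-null neurons, a far wider step than the other 3 probes show.

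Probe 30933 was the 1 probe of 36227 that passed the test. Its adjusted p was 0.0067 (limma, Benjamini-Hochberg over all probes), and the next smallest adjusted p was 0.316. No probe was called higher in necdin-null neurons by limma, although 1404 were higher at an unadjusted p under 0.05, and the unmoderated two-sample test called 0 probes in either direction after Benjamini-Hochberg adjustment. An exact two-sided permutation test of the probe alone gave p = 0.1, the smallest value that 3 against 3 samples allow. Left out in turn, necdin-null replicates 2 and 3 and wild-type replicates 1, 2 and 3 each took the adjusted p over the threshold, to at most 0.15, while the difference stayed between -4.19 and -4.08. A variance model that both follows the intensity level and is robust to outlying variances called 7 probes, of which 3 were higher and 4 lower.

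The other probes named by the rule set beforehand did not pass the threshold. Probe 22531 had a mean log2 intensity of 5.66 ± 0.03 in wild-type and 4.11 ± 0.28 in necdin-null neurons (SD, n = 3). The difference was -1.56 (SE 0.16), or 2.94-fold lower, with an adjusted p of 0.316 in limma. With the level-dependent and robust variance model its adjusted p was 6.6e-05, and without the dimmer probes, those at or below the median level, it was 0.0126. Among probes with higher values in necdin-null neurons, probe 9962 had 5.73 ± 0.16 against 4.86 ± 0.12 in wild-type neurons, a difference of 0.87 (SE 0.13) with an adjusted p of 0.434. The level-dependent and robust model gave this probe an adjusted p of 0.0165. Probe 8265 had 5.38 ± 0.04 against 4.91 ± 0.01, a difference of 0.47 (SE 0.08) with an adjusted p of 0.488.

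Differences of over 2 on the log2 scale, with the 3 necdin-null values all on one side of the 3 wild-type values, were found at 8 probes, 2 with lower and 6 with higher values in necdin-null neurons. The second of the lower probes, a dim one, averaged 5.17 in wild-type neurons, with an adjusted p of 0.325 in limma. Its necdin-null mean of 1.99 lay at the level of the dimmest 10% of probes (mean 1.96), so no fold is given. In 5 of the 6 with higher values, the gap between the groups was under 0.55 and the 3 values of 1 group spread over at least 2.18. In the remaining one the means were 4.56 and 2.22, the gap was 1.57 and the adjusted p was 0.451.

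**Figure D2:**
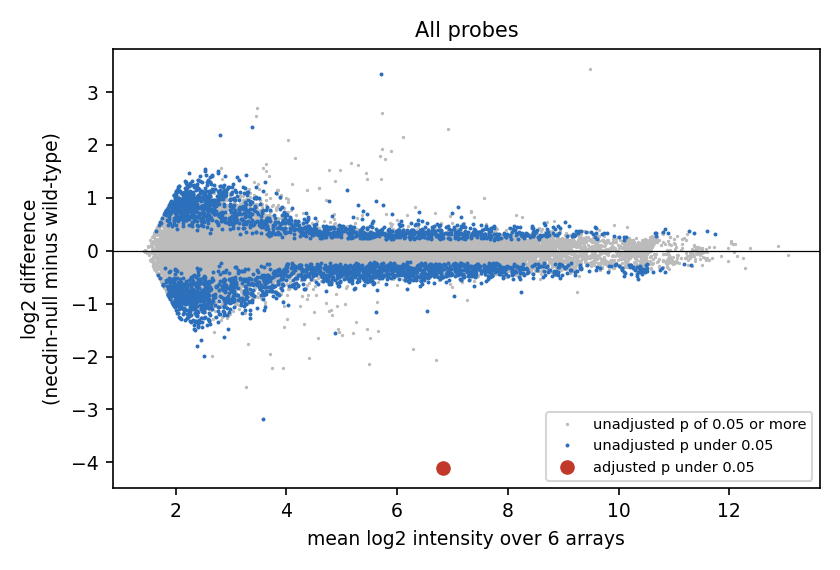
Difference between genotypes (log2, necdin-null minus wild-type, vertical axis) against the mean log2 intensity over the 6 arrays (horizontal axis), 1 point per probe. Grey points have an unadjusted p of 0.05 or more in limma, blue points one under 0.05, and the red point, probe 30933 at -4.11, passed the adjusted threshold.

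Most differences between the genotypes were smaller. Over all probes the median absolute difference was 0.178 (log2) and 95% lay within 0.731. The median absolute difference was 0.124 (log2) among the brighter probes, of which 95% lay within 0.395 and 99% within 0.549. With no effect and uniform p-values, 1811 probes would have an unadjusted p under 0.05, and 3242 had one (8.95%), of which 1404 were higher and 1838 lower in necdin-null neurons. Among the brighter probes there were 1621 of these, 616 higher and 1005 lower, where uniform p-values would give 906. The dimmer probes also had 1621. The 9 other divisions of the arrays into 3 and 3 gave 147 to 420 among the brighter probes and 1538 to 1926 over all probes. Most of theirs were thus dim, so 906 is no sound expectation for either part. Those divisions mix the genotypes, so a genotype difference adds to their spread. The 3 necdin-null values lay wholly above or wholly below the 3 wild-type values at 6254 probes (17.3%), where chance gives 10%. This share was 10.9% among the dimmer and 23.7% among the brighter probes, and it reached 31.1% in the ninth of 10 classes of probes ordered by level. Of these separated probes 325 differed by over 1 (log2), 175 with higher and 150 with lower values in necdin-null neurons, most of them dim. This count depended on the floor: it was 10 with log2(value + 16), 42 with a floor at the 20th percentile and 648 with no added floor. Among the brighter probes, 16 such probes differed by over 1 (log2), 9 with higher and 7 with lower values in necdin-null neurons. The 638 bright features that look like a control lattice had a median difference of 0.05 (log2) and array means of 10.34 to 10.40 in necdin-null and 10.30 to 10.31 in wild-type samples, while 4 of them (0.627%) had an unadjusted p under 0.05 and 0 were called.

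Whether the small differences recurred between animals was examined next. For each of the 9 choices of 1 necdin-null and 1 wild-type array, their difference was set against the mean difference of the other 4 arrays, which share no sample with it. Across the 18113 brighter probes, which are not independent of each other, the correlation averaged 0.292 and ranged from 0.179 to 0.361. When the 6 arrays were divided in the 9 other ways into 3 and 3, the average was at most 0.11. Single correlations reached 0.216, so the ranges overlapped. Each of these divisions contains 1 of the genotype correlations with its sign reversed. This lowers their averages, which are thus not independent of the genotype result. The genotype division had the highest average of the 10 divisions, which are too few for a share under 0.05.

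**Figure D3:**
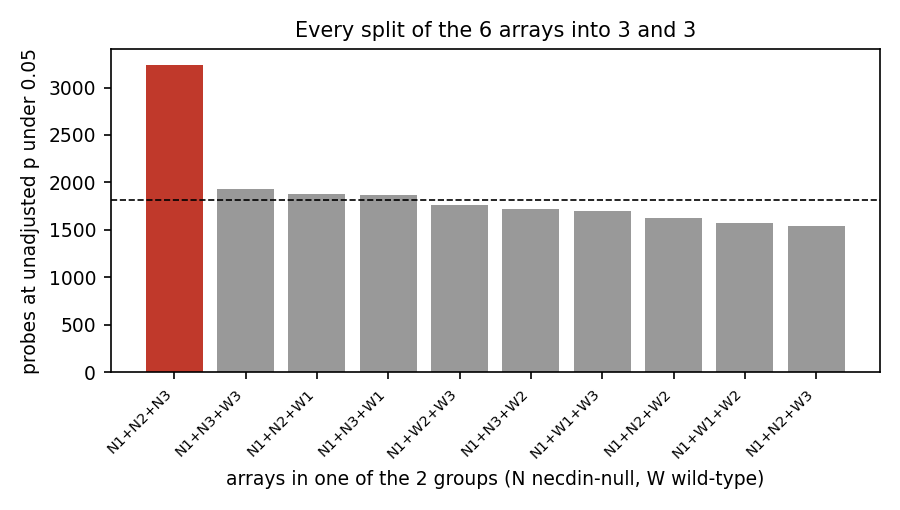
Number of probes at an unadjusted p under 0.05 in limma (vertical axis) for each of the 10 divisions of the 6 arrays into 3 and 3 (horizontal axis, named by the arrays in the group that holds necdin-null replicate 1). The genotype division, in red, gave 3242 probes, and the others gave between 1538 and 1926. The dashed line marks the 1811 expected without any effect if p-values are uniform.

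How often limma calls a change was measured on simulated data with the levels and spreads of these probes, with 200 probes changed together in each run. Among the brighter probes, limma called 0% of those changed by 0.5 (log2), 20.4% of those changed by 1, 88.4% of those changed by 2 and 99.2% of those changed by 4. Among the dimmer probes it called 5.6%, 27.2% and 34% of those changed by 1, 2 and 4. Changes of 0.5 and 1 were all rises and those of 2 and 4 all falls, so size and direction cannot be told apart. The floor of 1.45 (log2) cut many falls of dimmer probes short. From a level of 4.26 or less a fall of 4 cannot be reached, so the 27.2% and 34% do not hold for changes of full size. Of the unchanged probes it called 0.0136%, which were 49 false calls over the 10 runs. Rises of 2-fold or less were therefore mostly not called in this setting. Where fewer than 200 probes change, the Benjamini-Hochberg adjustment asks for smaller p-values. The shares above may thus be too high for these arrays, and they do not give the chance of calling a single changed probe.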

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

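The fall of probe 30933 kept its direction under 20 alternatives of limma's moderated fit, and its size lay between -4.11 and -3.49 (log2) in the 14 that used all arrays and between -4.19 and -3.99 with 1 array left out. Leaving out other probes, moving the floor, another variance prior and the block leave this probe's group means as they are, so they do not test the size. Of the other all-array fits, log2(value + 16) gave -3.49, array weights -4.08 and the running median subtracted -4.08. Probe 30933 passed the threshold in 13 of those 14 alternatives and in 1 of the 6 with an array left out, the one without necdin-null replicate 1 (adjusted p 0.022). The unmoderated two-sample test on all arrays gave it an adjusted p of 0.197, which did not pass. Its adjusted p was 0.067 without necdin-null replicate 2, 0.15 without replicate 3, and 0.141, 0.143 and 0.0741 without wild-type replicates 1, 2 and 3. Fewer arrays leave fewer residual degrees of freedom, while the difference hardly moved. With the replicate number as a block the difference was -4.11 with an adjusted p of 0.296, so that 0 probes were changed and 0 lower. The same-numbered samples' deviations correlated at 0.0786, 0.0869 and 0.0711 among the brighter probes. All 6 samples correlated best with their own number, a hint from the data and not from the design, and the samples share only a number. The count of changed probes, 1 in the main fit, was 2 without the dimmest 50% of the probes (2 lower), 7 with the level-dependent robust prior (3 higher and 4 lower) and 0 with the unmoderated test. With an array left out it ranged from 0 to 1, as did the counts of higher and of lower probes, since leaving out wild-type replicate 3 called 1 probe higher and 0 lower. The number of probes at an unadjusted p under 0.05 stayed within 1.5 times its main value in every alternative except the unmoderated test with a fold over 1.5 (784). Separated probes with a difference over 1 (log2) numbered 325 in the main fit, 122 and 16 without the dimmest 25% and 50%, 42 with the floor at the 20th percentile, 10 with log2(value + 16) and 648 with no added floor, so this count belongs mostly to dim probes, where the floor sets the size of a difference. Median centring and a second quantile normalization moved almost nothing, since the arrays already share 1 distribution, and say nothing about stability. The mean over a gene's probes, the tests of gene lists with estimated correlation or with another set test, and the window of genes around Ndn were not run, because no probe has a gene name.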

Other observations

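Chosen after the values had been seen were the test of failed spots for probe 30933, the divisions counted for separated probes, the count of two-state probes, the lattice levels, and the comparison of the 180 probes with the other necdin-null cultures.

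The fall of probe 30933 stood out in size. Spots reading at the deposited floor are argued against, since its lowest necdin-null intensity was 23.3, above the array median of 19.6. Spots that failed but read near background stay open, since no background values are given. A defect at one place of the arrays stays open: the 20 features nearest in the feature order had a median difference of -0.163 (log2), but deviations of neighbouring features correlated at only 0.016 to 0.043. These values lie above each of 100 shuffles, the bound set beforehand, but that bound was too low, since so weak a correlation does not show that neighbours in the order adjoin on the array. The genotype division called 1 probe and the 9 other divisions at most 0. But 10 divisions are too few for a share under 0.05, and 1 of them, the real one, reached this count. Without necdin-null replicate 1, the genotype division of the remaining arrays called 1 probe, and so did another division of them. Whether the probe reports the targeted gene, another gene of the region or a gene elsewhere stays open, because it carries no name. Two-state probes, with at least 2 arrays on each side of a gap over 2 (log2) and a spread within each side under 0.5 of the gap, numbered 14: 2 followed the genotype, and 12 divided the arrays in 10 other ways, with at most 2 probes sharing one.

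A second pattern is the excess of small differences. From the p-value distribution, the share of probes with some genotype difference was estimated at 20.6%, against at most 6.1% in the 9 other divisions of the arrays. The estimate takes p-values without effect as uniform, which 1 variance prior for all levels may not give. In the 9 other divisions, 147 to 420 brighter probes had an unadjusted p under 0.05 in limma, where uniform p-values would give 906. The median residual SD was 0.503 in the dimmest 10% of probes and 0.112 in the brightest 10%. Among the dimmer probes 85.5% were put as unchanged, though 10.9% were separated where chance gives 10%. The 20.6% is therefore no measured share. Probes at an unadjusted p under 0.05 numbered 3242 against at most 1926, and separated probes 6254 against at most 3822. In both cases 1 of the 10 divisions, the real one, gave as many, and 10 are too few for a share under 0.05. The other divisions are also not independent of the genotype result. Without ties each probe is separated by exactly 1 of the 10 divisions, so a high genotype count lowers the others. A genotype difference also adds to the spread within their groups, which lowers their counts under 0.05, here and in the comparisons below. As the whole cause, necdin-null replicate 1 alone and a smooth trend with level are argued against. Without necdin-null replicate 1 the genotype still gave 2779 probes, against at most 2193 for the other divisions of the remaining 5 arrays. With a level-dependent trend subtracted the genotype gave 3070 against at most 1895. That trend was small beforehand, as median differences in 10 classes by level lay between -0.028 and 0.031 (log2). With a trend along the feature order subtracted it gave 3046 against at most 1904. That order was not shown to follow places on the array, so this does not test effects of position. A biological hypothesis is that loss of necdin may shift many transcripts slightly. The 638 lattice features, which look like controls, were brighter on all 3 necdin-null arrays (mean log2 intensity 10.40, 10.36 and 10.34) than on the wild-type arrays (10.31, 10.30 and 10.31). They thus show a small common shift along the genotypes. Of these features 0.627% had an unadjusted p under 0.05 in limma and 0 were called. Their median difference of 0.05 (log2) was under the median standard error of the brighter probes, 0.12. A small difference does not account for so low a share, since uniform p-values without any effect would put a share of 0.05 there. For these bright features limma's p-values thus did not look uniform. The excess can therefore not be measured against the same expectation at every level. A difference between litters, culture days or hybridisation runs that coincided with genotype stays open, since the labels give none of these, and so does a difference in the makeup of the cultures, since cell type markers could not be looked up.

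The third pattern concerns 1 array. On necdin-null replicate 1, 180 of the brighter probes lay over 0.5 (log2) below all 5 other arrays and 30 above them, while the other arrays had between 16 and 47 below and between 4 and 16 above. The 180 probes were lower by a median of 0.8 on the log2 scale than the mean of the others. Complete loss of signal is argued against for most of them, as 2.22% of the 180 lay at the deposited floor. This count cannot show spots that failed in part. A trend with level is argued against, as 99.4% stayed below all others by over 0.5 once it was subtracted. A local defect is undecided: 15% had another of the 180 within 5 places in the feature order, between the bounds set for the test, where 1000 random sets of the same size had a median of 4.44% and an upper limit (95th percentile) of 8.89%. In the other 2 necdin-null cultures, 72.2% of the 180 were below the wild-type mean, against 47.8% of all brighter probes, so this culture may show more strongly something the others show weakly. No biological explanation was tested for it, because the design names none for a single animal.

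At 29 probes, a value at the deposited floor on 1 array stood beside values above 16 on the 5 others, with 2 to 10 such probes per array.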
